A study of Drosophila melanogaster with 24 samples.

How the data were processed

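Total RNA of Drosophila melanogaster was sequenced in 24 libraries from 8 groups of 3 replicates. The groups cross 2 tissues (indirect flight muscle, IFM, and ventral nerve cord, VNC), 2 stages (pupae at 30 h after puparium formation and adults at 15 days) and 2 treatments. Per the labels' protocols, larvae were fed from the first instar on food with 5 µM methylmercury chloride (MeHg) or with 0.01% DMSO as solvent control, and adults were kept on food without MeHg after eclosion. The sexes were mixed, animals were fixed in Methacarn before dissection, each replicate pooled tissue of 50 animals, and libraries were made with a stranded total RNA kit, per the labels.

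The deposited counts per gene are whole numbers for 17545 genes, and the submitters' processing notes name bcl2fastq 2.19.0, STAR 2.7.6a, Subread 2.0.1, featureCounts and the dm6 build. The notes do not state whether counting used the strand, so genes that overlap on opposite strands, and near-identical paralogs among the glutathione transferase, metallothionein, actin and Drosomycin-like genes, are uncertain. The authors also deposited a table of normalised counts, a signal in which the count of each gene is divided by 1 factor per library. The ratio of both tables was constant within a library to a relative deviation of 5.3e-15, and the factors ran from 0.554 to 1.49. All tests used the counts as deposited. Names came from a RefSeq gene table of the Release 6 plus ISO1 MT assembly through the locus tag, with a symbol for 17504 genes, and exonic lengths came from the union of exons in an Ensembl annotation of the same release, for 99.8% of the genes. Protein-coding genes of the mitochondrial genome have no counts in the files and were not analysed here.

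Library totals ran from 12.4 to 39.3, with a median of 30.5, in units of 1e6 counts. No pair of replicates among 24 pairs compared held identical columns, and their differences exceeded counting error (chi-square per degree of freedom 12.87 to 213.9).

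Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and robust dispersion. Every adjusted p of a gene below comes from this test with Benjamini-Hochberg adjustment over all genes tested, and genes at an adjusted p under 0.05 are called. MeHg effects, stage effects and their interaction were fitted on the 12 libraries of a tissue (residual degrees of freedom 8), with 11347 genes tested in IFM and 11870 in VNC. Tissue effects and the MeHg by tissue interactions were fitted on all 24 libraries (residual degrees of freedom 16, 12631 genes). CPM (counts per 1e6 counts of the library) are TMM-scaled and were averaged over the 3 libraries of a group. CPM printed with a fold change or its p are scaled within the libraries of that fit, and CPM of markers printed without one (elav, nSyb, alphaTry, roX1, roX2, Sxl, Yp1, Yp2 and Yp3 in adult VNC, and the marker figure) are scaled over all 24 libraries, so a gene can have slightly different values under both. The ± after a CPM is the SD over n = 3 and the ± after a log2 fold change is its standard error.

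A set of 32 gene lists (muscle, nerve cord, other cell types, metal and stress responses, metabolism and other tissues of the dissection) was fixed before the data were examined, of which 31 had at least 4 tested members. Lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The list p-values below are camera's. The genes named were chosen by a rule fixed before the data were examined: per MeHg comparison the 8 largest rises and 8 largest falls among called genes with separate group ranges, a mean of at least 5 CPM in the higher group and a symbol other than a CG or CR number; 6 and 6 for stage and tissue; up to 4 called members per list; and always Nlg1, cnc, Gclc, GstD1, MtnA, MtnB, kon, Mhc, Act88F and E(spl)mdelta-HLH. Only the main ones are printed.

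On simulated data with 200 changed genes, the test recovered 31.3%, 88.1% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold in pupal IFM (11134 genes), 47.8%, 86.6% and 98.5% in pupal VNC (11627 genes), 23.9%, 74.6% and 92.4% in adult IFM (11067 genes) and 52.2%, 89.6% and 100% in adult VNC (11705 genes). The changed genes were drawn only from genes of at least 5 CPM in the controls, so recovery below that level was not measured. These simulated libraries held no trend with gene length. Alternatives chosen before the data were examined were RLE scaling (the size factors of DESeq2), no low-count filter, DESeq2 1.42.0, limma voom with sample quality weights, ribosomal RNA and mitochondrial genes left out, a replicate block, a batch term from the title tags, only the 6 libraries compared, all 24 libraries, and each replicate left out in turn. Alternatives added later were the removal of each library's trend with gene length, marker levels as covariates, and 2 libraries with unusual marker levels left out together. The title tags are a number pair in each sample title whose meaning is not stated: in pupae replicate 1 of every group has 1 tag and replicates 2 and 3 another, and in adults only replicate 4 of the MeHg groups differs from the rest. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.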

Results

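The series measured gene expression by RNA sequencing in flight muscle and nerve cord of flies that had fed on methylmercury as larvae. Indirect flight muscle (IFM) comprises the dorsal longitudinal and dorsoventral muscles that power the wings, and the ventral nerve cord (VNC) holds the motor neurons that innervate them. MeHg is an organic mercury compound that acts on the developing nervous system. The design asks which genes respond to larval MeHg while the muscles form, at 30 h after puparium formation, which differ in adults after 15 days without MeHg, and whether both tissues respond alike. Each of the 8 groups had 3 libraries. Library totals, in units of 1e6 counts, were 17.1 to 29.4 in pupal IFM, 12.4 to 33.1 in pupal VNC, 24.3 to 36.3 in adult IFM and 35.1 to 39.3 in adult VNC. The lowest total belonged to replicate 2 of the MeHg pupal VNC.

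The control libraries carried the expression of their tissue. In pupae, IFM exceeded VNC in 3267 genes and lay below it in 4309, and in adults the numbers were 4424 and 4801 (12631 genes tested, edgeR quasi-likelihood test). The largest tissue differences in pupae included Act88F (log2 9.96 ± 1.15, adjusted p 3.35e-07), the flight muscle actin, Mhc (log2 9.18 ± 0.77, adjusted p 3.11e-09) and fln (log2 9.49 ± 0.71, adjusted p 5.4e-10) on the muscle side, with the neuropeptide Proc (log2 -7.45 ± 0.55, adjusted p 2.14e-10) and Tdc2 (log2 -8.36 ± 0.87, adjusted p 4.98e-08) on the nerve cord side. In adults TpnC4 (log2 10.13 ± 0.62, adjusted p 1.66e-11) and Act88F (log2 10.58 ± 1.18, adjusted p 1.84e-07) led in IFM and FMRFa (log2 -7.52 ± 0.61, adjusted p 1.55e-09) and Trhn (log2 -7.62 ± 0.29, adjusted p 4.73e-15) in VNC. RLE scaling shifted the median of all genes in the tissue comparisons by 0.171 in pupae and 0.139 in adults on the log2 scale, which is small beside these values but not for the balance of the counts. With RLE scaling 3812 genes were higher in IFM and 3880 lower in pupae, and 4849 and 4478 in adults. The 6 libraries alone gave 3907 and 3690 in pupae. Adults without VNC control 1, 2 or 3 gave 4758 and 4385, 4714 and 4131, and 4734 and 4369.

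From pupa to adult, 8445 genes changed in control IFM (4278 higher and 4167 lower in adults) and 7627 in control VNC (3761 higher and 3866 lower, with RLE scaling 3928 and 3815). The ecdysone-inducible gene ImpE2 was among the largest falls in both tissues, from 609 CPM (mean of n = 3) to 0.123 ± 0.00821 (SD) in IFM (edgeR adjusted p 5.47e-11) and from 399 ± 73.8 to 0.0381 ± 0.0448 in VNC (adjusted p 3.77e-09). Yp1, a yolk protein of adult females, was among the largest rises (log2 17.47 ± 1.47, adjusted p 2.19e-06 in IFM and log2 13.63 ± 0.75, adjusted p 5.58e-08 in VNC). These developmental and tissue differences set the scale for the MeHg effects, which were far smaller in number.

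**Figure D1:**
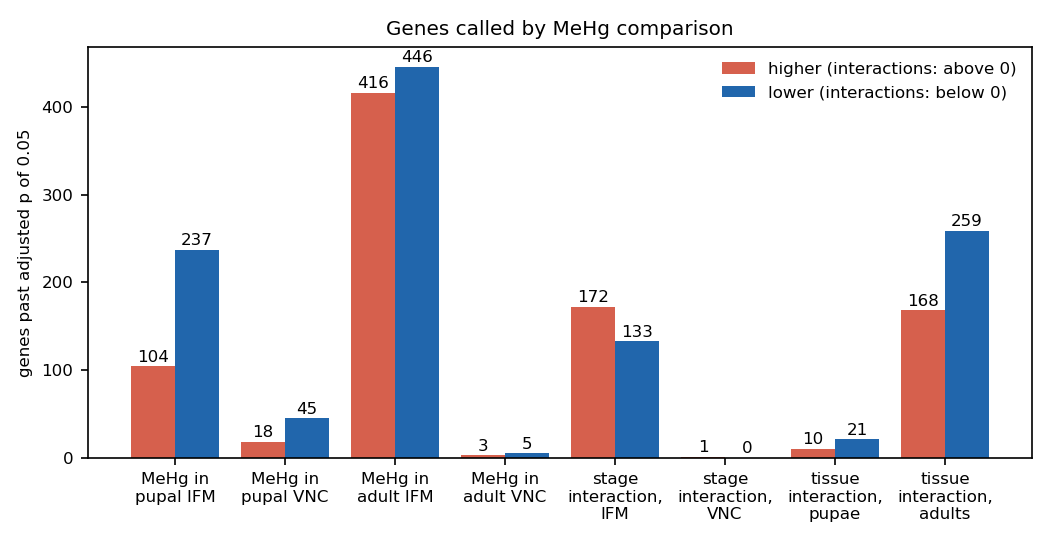
Genes past an adjusted p of 0.05 in the MeHg comparisons and their interactions (vertical axis, number of genes; horizontal axis, comparison), higher in red and lower in blue. Adult IFM had 416 higher and 446 lower genes and adult VNC 3 and 5.

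The first question was which genes MeHg moved while the flight muscle formed. In pupal IFM, 5 genes of the myoblast fusion and muscle identity list rose, with 1 of the cell cycle list, 2 of the Notch list and 2 of the cell death list, while 3 genes of oxidative phosphorylation and 4 of the glutathione pathway fell. Of 31 lists, camera called 12 with the preset correlation and 0 with the estimated one, and fry called 5. MeHg called 341 of 11347 genes, 104 higher and 237 lower, and 112 of them changed 2-fold or more. The group ranges of all 341 were separate, which 28.7% of all tested genes showed and chance gives for 10%. The MeHg libraries also carried relatively more counts of long genes: across 7128 genes of at least 5 CPM the log2 fold change rose with exonic length (Spearman 0.47, across genes, which are not independent replicates), from a median of -0.24 in the shortest 10% to 0.20 in the longest 10%, and the lists below differ in length. The count without 1 library was 190 (control 1), 146 (control 2), 181 (MeHg 1), 181 (MeHg 2) and 101 (MeHg 3). It was 0 with a replicate block, 154 with the title tag as batch, 523 with the 6 libraries alone, 587 with all 24, 873 by voom and 949 by DESeq2.

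The fusion receptors sns and rst, the fusion effector mbc and the actin regulator Vrp1, which form and open the contact between fusing myoblasts, rose in pupal IFM. The cell surface receptor sns (Dmel_CG33141, chromosome 2R, 8798489 to 8856091) rose from 177 ± 52.3 CPM in controls to 527 ± 124 with MeHg (SD, n = 3; log2 1.57 ± 0.23, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 0.00662). Its partner rst rose by 1.08 ± 0.16 (log2, adjusted p 0.00662), Vrp1 by 1.17 ± 0.15 (adjusted p 0.00378), mbc by 0.85 ± 0.16 (adjusted p 0.0156) and tx by 0.53 ± 0.10 (adjusted p 0.0189). The fusion and muscle identity list had a median log2 fold change of 0.43 over 24 genes, 23 of them above 0, with 5 called over all genes and 10 adjusted over the list alone (camera adjusted p 2.95e-11 with the preset correlation and 0.164 with the estimated one). With the length trend of each library removed the median was 0.26, and the list has a median exonic length of 5858.5 bases against 1933 over all tested genes.

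Of 34 genes of the contractile apparatus, 1 was called in pupal IFM, the flight muscle protein fln, and their list did not pass (camera adjusted p 0.134). Mhc (log2 -0.12 ± 0.19, adjusted p 0.793) and Act88F (log2 -0.24 ± 0.20, adjusted p 0.556) did not pass, kon (log2 0.30 ± 0.14, adjusted p 0.255) and the synaptic adhesion gene Nlg1 (log2 0.51 ± 0.18, adjusted p 0.162) did not pass either, and fln fell by 1.09 ± 0.23 (log2, adjusted p 0.0289). The neuromuscular junction list was called higher, with trio (log2 0.40 ± 0.08, adjusted p 0.031) and Fas2 (log2 0.34 ± 0.08, adjusted p 0.0475) called. Its median was 0.20 (camera adjusted p 0.000816, with the estimated correlation 0.206), and 0.128 without control 2. The muscle attachment list (median 0.17, camera adjusted p 0.0214, estimated 0.415), the neuron list (0.32, 0.00546, estimated 0.756) and the haemocyte list (0.24, 0.0374, estimated 0.753) were also called higher, and these and the junction list lost the call with the length trend removed. The attachment list also lost it without control 2 or MeHg 3 (adjusted p 0.0523 and 0.0917), the neuron list without MeHg 2 (0.0937, median 0.162) and the haemocyte list without control 2, control 3 or MeHg 3 (0.0959, 0.178 and 0.103). The neuron median was 0.512 without control 1 and 0.199 without control 2.

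The cell cycle, Notch and cell death lists were called higher in pupal IFM with the preset correlation, through few genes that passed singly. The cell cycle list had a median of 0.49, with 32 of 33 genes above 0, feo called over all genes (log2 0.92 ± 0.21, adjusted p 0.0416) and 4 adjusted over the list alone (camera adjusted p 1.06e-09, estimated 0.265). The Notch list had a median of 0.37, with neur (log2 0.50 ± 0.11, adjusted p 0.0341) and E(spl)m7-HLH (log2 1.45 ± 0.32, adjusted p 0.0354) called and 6 adjusted over the list alone (camera adjusted p 6.34e-07, estimated 0.164), and E(spl)mdelta-HLH did not pass (log2 0.36 ± 0.43, adjusted p 0.717). The cell death genes hid (log2 0.69 ± 0.16, adjusted p 0.0413) and rpr (log2 0.64 ± 0.15, adjusted p 0.0492) rose, within a list of median 0.18 (camera adjusted p 0.000451, estimated 0.206). Medians with the length trend removed were 0.55, 0.42 and 0.20, and all 3 lists kept the call. The antimicrobial list was called higher as well (median 0.34, camera adjusted p 0.0163, estimated 0.756), with no member called, and lost the call without control 3 or MeHg 3 (adjusted p 0.316 and 0.368, medians 0.215 and 0.024). The ecdysone-responsive transcription factor Eip93F rose by 0.55 ± 0.10 (log2, adjusted p 0.0141).

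The oxidative phosphorylation list was called lower in pupal IFM, with 3 of 69 genes passing singly. All 69 tested nuclear genes of oxidative phosphorylation had a log2 fold change below 0, with a median of -0.33 (camera adjusted p 3.19e-18, estimated 0.474). ND-B16.6 (log2 -0.48 ± 0.10, adjusted p 0.031), UQCR-Q (log2 -0.68 ± 0.15, adjusted p 0.0387) and ND-30 (log2 -0.59 ± 0.14, adjusted p 0.0425) were called over all genes and 10 adjusted over the list alone. The list is short in sequence (median 862 bases), and with the length trend removed its median was -0.15. The glycolysis list was called lower (median -0.18, camera adjusted p 0.0163, estimated 0.74), with Gpo1 called (log2 -0.75 ± 0.14, adjusted p 0.0156), and so was the proteasome list (median -0.12, camera adjusted p 0.0268, estimated 0.756), which turned to 0.03 with the length trend removed. Both lost the call without single libraries, glycolysis without control 2 or MeHg 2 (adjusted p 0.0523 and 0.0505, median -0.118 without control 2) and the proteasome without control 1, control 2, control 3 or MeHg 3 (0.0776, 0.0504, 0.0616 and 0.16). Counts on the mitochondrial genome took 2.93%, 2.50% and 1.80% of the control libraries and 1.39%, 1.51% and 1.42% of the MeHg libraries. The files count no protein gene of that genome, and rRNA genes took nearly the same shares (3.18%, 2.87% and 1.86% against 1.44%, 1.68% and 1.55%). Both shares include the mitochondrial rRNA genes, so they are not independent, and they do not measure respiration. Whether mitochondrial rRNA itself fell, or more rRNA was left in the control libraries, was not tested.

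Single detoxification genes fell in pupal IFM although their lists did not pass. GstE13 (Dmel_CG11784, chromosome 2R, 9122125 to 9123309), a glutathione transferase, fell from 19.8 ± 1.35 to 6.24 ± 0.81 CPM (log2 -1.66 ± 0.14, adjusted p 0.000869), with falls of GstZ1 (log2 -1.38 ± 0.14, adjusted p 0.00107), Prx6a (log2 -1.77 ± 0.20, adjusted p 0.00206) and GstO2 (log2 -0.47 ± 0.10, adjusted p 0.023). The copper importer Ctr1A fell (log2 -0.64 ± 0.10, adjusted p 0.0086), as did the methyltransferase Bhmt (log2 -1.51 ± 0.20, adjusted p 0.00379) and Gip (log2 -2.03 ± 0.26, adjusted p 0.00378). GstD1 (log2 0.06 ± 0.14, adjusted p 0.862), Gclc (log2 -0.22 ± 0.19, adjusted p 0.573), their regulator cnc (log2 0.06 ± 0.08, adjusted p 0.741), MtnA (log2 -1.03 ± 0.76, adjusted p 0.507) and MtnB (log2 0.77 ± 0.77, adjusted p 0.646) did not pass.

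**Figure D2:**
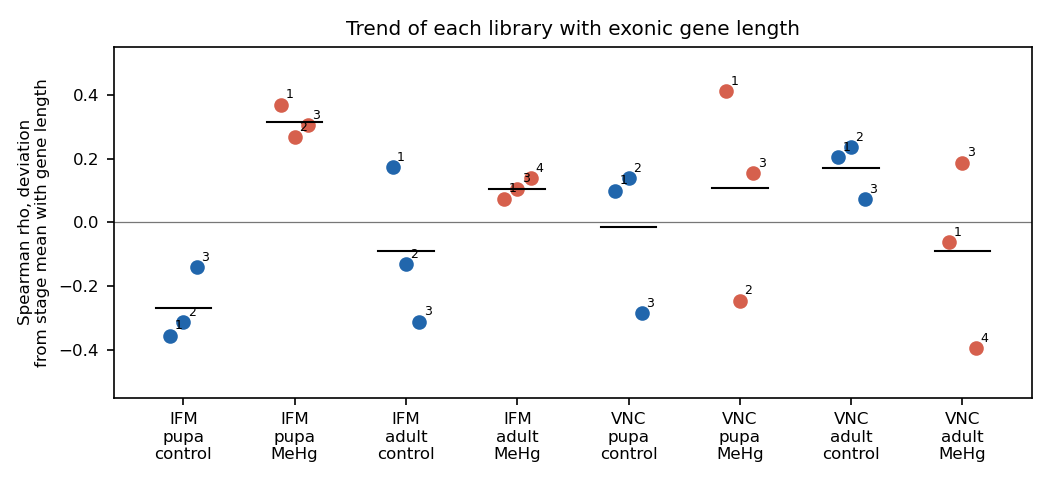
Spearman correlation across genes of each library's deviation from the mean of its tissue and stage with exonic gene length (vertical axis), by group (horizontal axis); points are libraries with their replicate number and bars are means. The 3 pupal IFM controls lie at -0.356, -0.313 and -0.141 and the 3 MeHg libraries at 0.369, 0.267 and 0.305.

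The second question was the response of the nerve cord at the same stage. In pupal VNC a metallothionein, neuropeptide genes and immune peptides were called higher with MeHg and 45 genes lower, and the neuron list was the only list called lower. Of 31 lists, camera called 8 with the preset correlation and 0 with the estimated one, and fry called 0. MeHg called 63 of 11870 genes, 18 higher and 45 lower, with separate group ranges for all 63 (14.3% of all genes, chance 10%). The length trend between the groups was near 0 (Spearman 0.03, across genes), but single libraries had trends in opposite directions. The controls stood at 0.099, 0.139 and -0.285 and the MeHg libraries at 0.412, -0.246 and 0.155 (Spearman of each library's deviation with length). The count without 1 library was 5 (control 1), 16 (control 2), 11 (control 3), 41 (MeHg 1) and 33 (MeHg 3). It was 0 with a replicate block and with the 6 libraries alone, and 28 with all 24 libraries, 1 higher and 27 lower. No filter gave 30, the title tag as batch 31, voom 101 and DESeq2 224. MtnA, which binds metals, rose from 18.1 ± 4.06 to 67.8 ± 26.1 CPM (log2 1.90 ± 0.27, adjusted p 0.0188), and the metal list had a median of 0.35 (camera adjusted p 0.000246, estimated 0.285; 0.227 without control 1 and 0.205 without MeHg 2), with 1 gene called over all genes and 3 adjusted over the list alone. MtnB did not pass (log2 1.83 ± 0.77, adjusted p 0.531).

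The neuropeptide genes Lk (log2 1.05 ± 0.16, adjusted p 0.0202) and Proc (log2 0.70 ± 0.12, adjusted p 0.0328) rose in pupal VNC. Arc1 (Dmel_CG12505) rose there from 438 ± 41.3 to 896 ± 270 CPM (log2 1.03 ± 0.19, adjusted p 0.0446). Its counts were not particular to the nerve cord. Scaled over all 24 libraries, pupal controls had 249 to 305.5 CPM in IFM and 363.5 to 446 in VNC. Adult controls had 1617 to 1888 CPM in IFM and 597 to 704.4 in VNC. The neuropeptide list was called higher (median 0.19, mean -0.03, camera adjusted p 0.000246, estimated 0.285; median 0.124 without MeHg 2), with 2 genes called over all genes and 4 adjusted over the list alone. The immune genes Drsl3 (log2 3.15 ± 0.46, adjusted p 0.0226), Drsl4 (log2 3.37 ± 0.41, adjusted p 0.00746) and edin (log2 1.28 ± 0.22, adjusted p 0.0304) rose, within a list of median 0.29 (camera adjusted p 0.0407, estimated 0.915; 0.371 without control 2 and 0.952 without MeHg 3). The median was 0.459 without MeHg 1 and 0.078 without MeHg 3. Drsl4 stayed below 1 CPM in both groups, at 0.0559 ± 0.0238 and 0.605 ± 0.237.

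The named falls in pupal VNC included rec (log2 -1.72 ± 0.15, adjusted p 0.00223), c(3)G (log2 -1.35 ± 0.25, adjusted p 0.0444) and Fancm (log2 -0.96 ± 0.11, adjusted p 0.00626), Cep290 (Dmel_CG13889; log2 -1.23 ± 0.13, adjusted p 0.00296) and GstE13 (log2 -1.12 ± 0.13, adjusted p 0.00657). The muscle glutamate receptor GluRIIA fell (log2 -0.88 ± 0.11, adjusted p 0.00884). Ribosomal protein genes had a median of 0.30, with 84 of 86 above 0 (camera adjusted p 1.04e-19, estimated 0.915), and none was called singly. The sarcomere list (median 0.20, camera adjusted p 0.00803, estimated 0.915), the cell cycle list (0.10, 0.0161, estimated 0.915) and the glycolysis list (0.09, 0.0473, estimated 0.915) were called higher and the neuron list lower (median -0.10, camera adjusted p 0.0407, estimated 0.915). The neuron list lost the call without MeHg replicate 2, the library of the lowest total, in which elav stood at 345 CPM against 568 and 570 in the other MeHg libraries and nSyb at 492 against 686 and 719. Without it the median was 0.001 (adjusted p 0.544), without control 2 the adjusted p was 0.371, and without MeHg 1 the median was -0.215. Other calls were lost without MeHg 1 (sarcomere, 0.344), control 2 or MeHg 3 (cell cycle, 0.203 and 0.3), and control 1, control 3 or MeHg 2 (glycolysis, 0.241, 0.0983 and 0.987), and the ribosomal median was 0.063 without MeHg 2. The sarcomere median was 0.129, 0.116 and 0.32 without MeHg 1, 2 and 3. The cell cycle median was 0.162 without control 3 and 0.166 without MeHg 1, and that of glycolysis -0.001 without MeHg 2. Mhc (log2 1.77 ± 0.77, adjusted p 0.548) and Act88F (log2 2.36 ± 1.11, adjusted p 0.585) varied between libraries and did not pass. cnc (log2 0.02 ± 0.08, adjusted p 0.964), Gclc (log2 0.04 ± 0.11, adjusted p 0.942), GstD1 (log2 0.17 ± 0.22, adjusted p 0.857), kon (log2 -0.10 ± 0.13, adjusted p 0.859), Nlg1 (log2 -0.22 ± 0.37, adjusted p 0.894) and E(spl)mdelta-HLH (log2 0.72 ± 0.68, adjusted p 0.8) did not pass.

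The third question was what remained in adult muscle after 15 days without MeHg. In adult IFM 22 genes of oxidative phosphorylation and 4 of the sarcomere were called lower with MeHg. Called higher were 7 immune genes, 5 of the cytochrome P450 list and 1 of the gut list. Of the glutathione list 6 were higher and 4 lower, and of the metal list 4 higher and 1 lower. Gut RNA and a larger share of males could not be told apart from an effect of MeHg in these calls, as weighed below. Of 31 lists, camera called 8 with the preset correlation and 0 with the estimated one, and fry called 0. MeHg called 862 of 11347 genes, 416 higher and 446 lower, of which 860 had separate group ranges (27.1% of all genes, chance 10%) and 300 changed 2-fold or more. The count was 324 without control 3, 446 without MeHg 1 and 210 without MeHg 4. The near balance of both directions held with neither a replicate block (238 higher and 93 lower), the title tag as batch (56 and 25) nor the 6 libraries alone (101 and 51). Without MeHg 4 it was 135 and 75. DESeq2 called 1522 and the fit of all 24 libraries 1410, and with the gut list or roX1 as covariate 50 and 6 genes were called. Among markers of sex the male-specific RNA roX1 (lncRNA:roX1) rose from 931 ± 212 to 1835 ± 193 CPM (log2 0.98 ± 0.25, adjusted p 0.0402) and msl-2 rose (log2 0.46 ± 0.12, adjusted p 0.0417), while the other male-specific RNA, roX2, did not pass (log2 0.27 ± 0.32). The female yolk gene Yp1 stood at 16809 ± 2088 CPM in controls and 8341 ± 2818 with MeHg (log2 -1.01 ± 0.73, adjusted p 0.445). It did not pass, nor did Yp2 (log2 -1.07 ± 0.42, adjusted p 0.148), Yp3 (log2 -0.93 ± 0.26, adjusted p 0.0518) and the sex determination gene Sxl (log2 -0.47 ± 0.14, adjusted p 0.0638), although the group ranges of these 4 were separate. The sexes were mixed, per the labels, and their share per library is not given.

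Of 34 sarcomere genes 4 fell in adult IFM. Act88F (Dmel_CG5178, chromosome 3R, 15439969 to 15442177) fell from 3862 ± 916 to 1587 ± 338 CPM (log2 -1.28 ± 0.20, adjusted p 0.00776), with Mlp60A (log2 -1.37 ± 0.21, adjusted p 0.00599), the titin-related sls (log2 -0.77 ± 0.15, adjusted p 0.0154) and Strn-Mlck (log2 -0.66 ± 0.15, adjusted p 0.0252), while Mhc did not pass (log2 -0.14 ± 0.19, adjusted p 0.714). The sarcomere list as a whole did not pass (median -0.14, camera adjusted p 0.0756), with 4 genes called over all genes and 7 adjusted over the list alone. The attachment and basement membrane genes SPARC (log2 -0.81 ± 0.14, adjusted p 0.0102), Ndg (log2 -1.06 ± 0.19, adjusted p 0.0107) and Ilk (log2 -0.75 ± 0.14, adjusted p 0.0136) fell and Pgant3 rose (log2 0.94 ± 0.17, adjusted p 0.0104). Nlg1 (log2 -0.14 ± 0.18, adjusted p 0.698) and kon (log2 -0.03 ± 0.14, adjusted p 0.926) did not pass.

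The oxidative phosphorylation list was called lower in adult IFM. Of 69 nuclear genes of oxidative phosphorylation 63 lay below 0, with a median of -0.39, 22 called over all genes and 36 adjusted over the list alone (camera adjusted p 4.4e-14, estimated 0.723). ND-13B (log2 -0.81 ± 0.14, adjusted p 0.00986), ND-49 (log2 -0.61 ± 0.11, adjusted p 0.0123) and UQCR-14 (log2 -0.83 ± 0.15, adjusted p 0.013) were among them. With the length trend removed (Spearman 0.15 before, across genes) the median was -0.23. The ribosomal protein list was called lower (median -0.12, camera adjusted p 0.0102, estimated 0.889), which turned to 0.07 with the length trend removed and lost the call without control 2, control 3 or MeHg 3 (adjusted p 0.409, 0.0967 and 0.483). Its median was -0.236, -0.069, -0.212 and -0.062 without control 1, control 2, MeHg 1 and MeHg 3.

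Single immune, metal and detoxification genes rose in adult IFM, where markers of gut and Malpighian tubule also lay higher. The tubule gene Uro averaged 2.24 ± 3.13 CPM in controls and 55.6 ± 37.4 with MeHg, with separate ranges but without passing (log2 4.62 ± 1.21, adjusted p 0.0635), and Mal-A1 of the gut list rose. With that list as covariate 50 of the 862 calls were left. Def kept its call there, and the other called genes of this paragraph lost it with fold changes of the same sign. Over all 416 genes called higher, that covariate took the median log2 fold change from 1.315 to 1.118 and the median standard error from 0.252 to 0.293. The antimicrobial peptide Def rose from 1.30 ± 0.13 to 13.8 ± 6.77 CPM (log2 3.40 ± 0.49, adjusted p 0.00618) and Drs from 18.8 ± 6.31 to 148 ± 13.9 (log2 2.98 ± 0.60, adjusted p 0.0211), within a list of median 0.48 with 7 genes called over all genes and 13 adjusted over the list alone (camera adjusted p 0.000445, estimated 0.723). The metal list had a median of 0.46 (camera adjusted p 0.00421, estimated 0.723), with MtnE (log2 2.23 ± 0.47, adjusted p 0.0208), ZnT35C (log2 4.33 ± 1.08, adjusted p 0.0401) and Fer1HCH (log2 0.63 ± 0.15, adjusted p 0.0323) higher, Ctr1A lower (log2 -0.47 ± 0.10, adjusted p 0.0224), and MtnA (log2 1.19 ± 0.74, adjusted p 0.372) and MtnB (log2 3.12 ± 1.23, adjusted p 0.152) not passing. The glutathione list had a median of 0.24 (camera adjusted p 0.0337, estimated 0.723), with GstD10 (log2 2.25 ± 0.34, adjusted p 0.00549), GstO2 (log2 0.54 ± 0.09, adjusted p 0.0102) and GstD1 (log2 0.52 ± 0.14, adjusted p 0.0424) higher and GstE13 lower (log2 -0.70 ± 0.13, adjusted p 0.013). cnc (log2 -0.28 ± 0.08, adjusted p 0.0569) and Gclc (log2 0.21 ± 0.17, adjusted p 0.5) did not pass. The cytochrome P450 list had a median of 0.32 (camera adjusted p 0.000445, estimated 0.723), led by Cyp6a18 (log2 5.90 ± 0.71, adjusted p 0.00434). Without control 1 the immune (adjusted p 0.126), glutathione (0.3) and cytochrome P450 (0.0613) lists lost the call, and the glutathione list also without MeHg 1 (0.15, median 0.131), where the cytochrome P450 median was 0.213.

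The gut list was called higher in adult IFM, with 1 of 20 genes passing singly. It had a median of 0.93 (camera adjusted p 9.63e-05, estimated 0.723; 1.717 without control 2), and the amylase-family gene Mal-A1 rose from 285 ± 215 to 1581 ± 557 CPM (log2 2.47 ± 0.59, adjusted p 0.0365). Outside that list, large rises included Peritrophin-15a (log2 6.47 ± 1.16, adjusted p 0.0145), mat (log2 5.79 ± 1.18, adjusted p 0.0213) and LysX (log2 5.48 ± 0.97, adjusted p 0.0137). The trypsin alphaTry ran from 137 to 1690 CPM in the controls and averaged 1919 ± 590 with MeHg. The cell cycle list had a median of 0.48 (camera adjusted p 0.000854, estimated 0.723; 0.835 without control 1 and 0.309 without control 2), with mira (log2 1.69 ± 0.34, adjusted p 0.0163), feo (log2 1.62 ± 0.24, adjusted p 0.00541) and RnrS (log2 0.98 ± 0.16, adjusted p 0.00788) called, and Sox21a rose (log2 6.23 ± 1.03, adjusted p 0.013). The Notch genes neur (log2 0.73 ± 0.11, adjusted p 0.00629) and E(spl)m3-HLH (log2 1.69 ± 0.38, adjusted p 0.0238) rose, and E(spl)mdelta-HLH did not pass (log2 0.09 ± 0.54, adjusted p 0.948). The stress-responsive Ets21C (log2 1.84 ± 0.22, adjusted p 0.0037) and Mmp1 (log2 1.34 ± 0.24, adjusted p 0.012) rose, while rpr fell (log2 -0.70 ± 0.16, adjusted p 0.0258). The neuropeptide CNMa fell from 37.1 ± 11.0 to 4.57 ± 2.89 CPM (log2 -3.03 ± 0.51, adjusted p 0.0104).

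**Figure D3:**
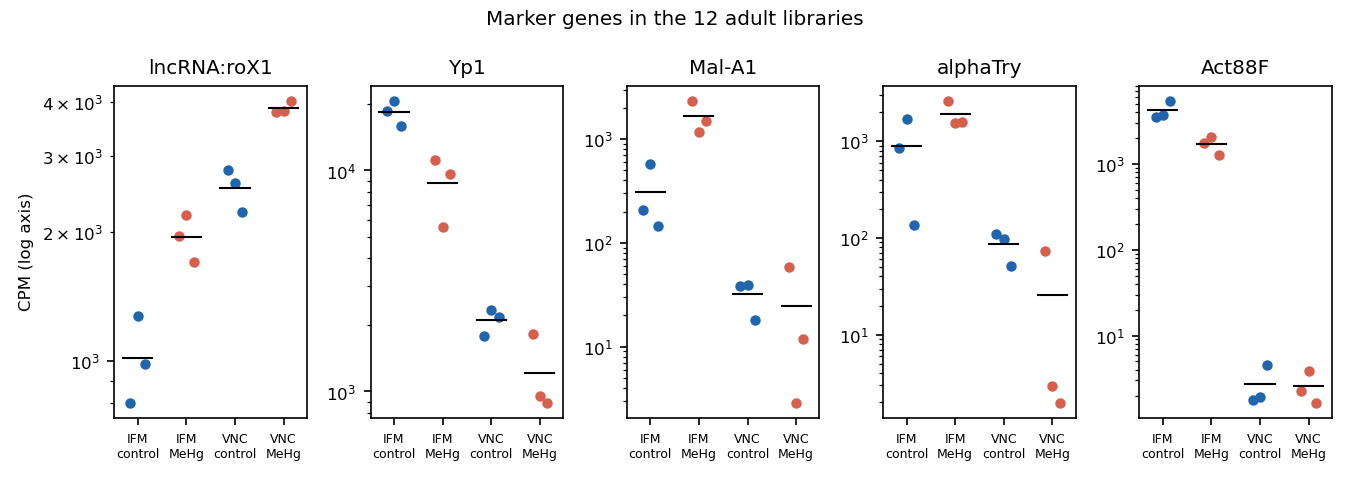
CPM on a log axis of 5 marker genes in the 12 adult libraries, controls in blue and MeHg in red, bars at group means. In IFM roX1 lay at 798 to 1270 CPM in controls and 1700 to 2180 with MeHg, Mal-A1 at 145 to 583 and 1180 to 2330.

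The adult nerve cord showed few changes that passed the test. MeHg called 8 of 11870 genes in adult VNC, 3 higher and 5 lower, all 8 with separate group ranges (23.6% of all genes, chance 10%). At an unadjusted p under 0.05 there were 1610 genes, DESeq2 called 276 (154 higher, 122 lower) and limma voom with sample weights 88 (56 and 32). The 6 libraries alone gave 27 (15 and 12), and the gut list as covariate 12 (10 and 2), of which 1 was among the main 8. With roX1 as covariate 0 genes were called, and with the sarcomere list 3. A replicate block gave 2, of which 1 was among the main 8. In this tissue and stage the 2 replicate numbers shared by both groups correlated (0.342 and 0.345, other pairs -0.354 to 0.119). The count without 1 library was 4 (control 1), 5 (control 2), 2 (control 3), 25 (MeHg 1, 2 higher and 23 lower), 2 (MeHg 3) and 15 (MeHg 4, 11 and 4). With the title tag as batch 8 genes were called as well, 7 higher and 1 lower, but only 1 of them was among the main 8. Cep290 fell from 8.40 ± 0.77 to 3.17 ± 0.10 CPM (log2 -1.41 ± 0.12, adjusted p 0.00185), as in pupal VNC, and CNMa fell from 3.88 ± 1.23 to 0.379 ± 0.067 CPM (log2 -3.34 ± 0.40, adjusted p 0.0193), as in adult IFM. The gut list lay at a median of -1.68 (camera adjusted p 9.59e-11, estimated 0.72), with 0 genes called over all genes and 4 adjusted over the list alone, the oxidative phosphorylation list at 0.21 (camera adjusted p 1.06e-05, estimated 0.901) and the sarcomere list at -0.24 (camera adjusted p 0.00383, estimated 0.901). The gut median was -4.12 without MeHg 1 and that of oxidative phosphorylation 0.115 without control 2. The sarcomere median was -0.384 without control 1, 0.086 without control 3 (adjusted p 0.377), -0.498 without MeHg 3 and 0.017 without MeHg 4 (0.897). Genes of short exonic length were relatively higher (Spearman -0.23, across genes), with a median log2 fold change of 0.144 in the shortest 10%. The oxidative phosphorylation list is short in sequence (median 862 bases against 1892 over all tested genes). Part of its median of 0.21 may therefore be this trend. alphaTry averaged 85.7 ± 30.0 CPM in controls and 25.9 ± 40.6 with MeHg, roX1 2532 ± 283 and 3875 ± 127, roX2 140.6 ± 37 and 267.5 ± 38.2, and Sxl 670.8 ± 44.8 and 684.4 ± 38.1. Both roX ranges were separate, and none of these 4 genes passed. The yolk genes lay lower with MeHg, with overlapping ranges. Yp1 averaged 2099 ± 277 CPM in controls and 1218 ± 521 with MeHg, Yp2 1393 ± 211 and 817.6 ± 339, and Yp3 1382 ± 171 and 966.9 ± 412. Among the genes always examined, MtnA (log2 0.18 ± 0.25, adjusted p 0.787), GstD1 (log2 0.12 ± 0.22, adjusted p 0.84), cnc (log2 0.12 ± 0.08, adjusted p 0.518), Gclc (log2 0.06 ± 0.10, adjusted p 0.835), Nlg1 (log2 -0.31 ± 0.39, adjusted p 0.746) and kon (log2 -0.09 ± 0.13, adjusted p 0.8) did not pass.

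**Figure D4:**
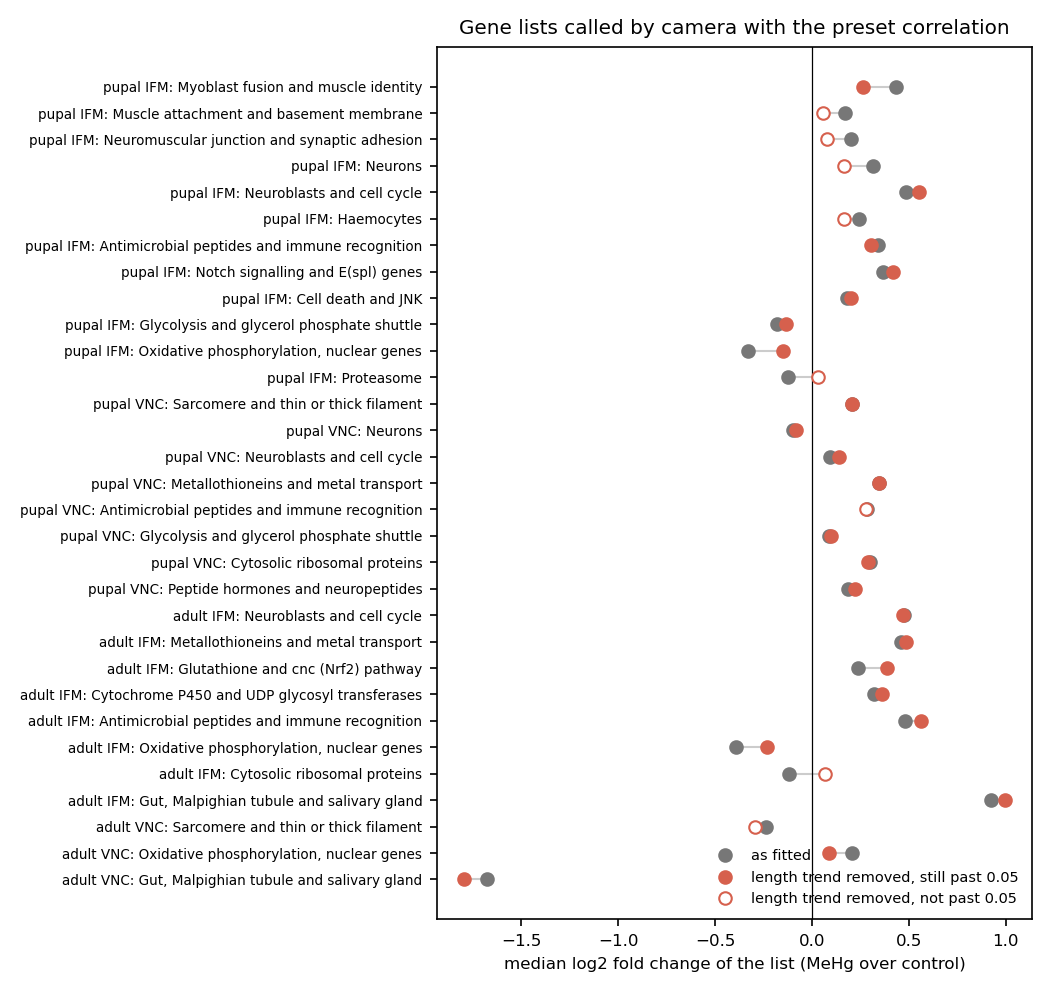
Median log2 fold change (horizontal axis) of each list called by camera with the preset correlation (vertical axis, by comparison), as fitted in grey and with the length trend of each library removed in red; open points no longer passed. Oxidative phosphorylation in pupal IFM moved from -0.33 to -0.15 and the proteasome from -0.12 to 0.03.

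The difference of the MeHg effect between stages and tissues was tested itself. In IFM it passed between adults and pupae for 305 genes, which became 0 with the title tag as a batch term and 18 with a replicate block (1010 by DESeq2, 2233 at an unadjusted p under 0.05). In adult IFM only MeHg 4 carries a different tag. Of the 305, 117 were also called in pupal IFM, 171 in adult IFM and 28 in neither. They included sns (difference adult minus pupa, log2 -1.63 ± 0.33, adjusted p 0.0323), rpr (log2 -1.34 ± 0.22, adjusted p 0.0199), Bhmt (log2 1.61 ± 0.28, adjusted p 0.0205) and Def (log2 2.89 ± 0.63, adjusted p 0.0435). Act88F, which was called in adults only, did not pass this test (log2 -1.04 ± 0.28, adjusted p 0.0817). In VNC the difference passed for 1 gene, CG34215 (log2 3.54 ± 0.35, adjusted p 0.0063), with 1574 genes at an unadjusted p under 0.05 and 219 called by DESeq2. Between tissues, the difference passed for 31 genes in pupae, among them sns (IFM minus VNC, log2 1.69 ± 0.31, adjusted p 0.0188), Vrp1 (log2 1.27 ± 0.21, adjusted p 0.01) and Gpo1 (log2 -0.86 ± 0.16, adjusted p 0.0177), and for 427 genes in adults, among them neur (log2 0.58 ± 0.16, adjusted p 0.0488) and Mov10 (log2 5.26 ± 0.95, adjusted p 0.00655). In pupae RLE scaling gave 59 and DESeq2 258, and in adults no filter gave 283, the title tag as batch 275, voom 945 and DESeq2 1177. Leaving out 1 library gave 39 (without pupal IFM MeHg 3) to 447 genes for stage in IFM, 0 (without pupal VNC control 1) to 11 (without pupal VNC MeHg 1) for stage in VNC, 16 (without pupal IFM control 2) to 56 (without pupal IFM control 3) for tissue in pupae and 141 (without adult IFM MeHg 4) to 716 (without adult IFM control 2) for tissue in adults.

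Few genes were called in more than 1 comparison. In pupae 12 genes were called in both tissues, where independent lists would share 1.89, and 11 of them were lower in both. The value of 1.89 takes the tissues as independent, whereas MeHg pupae of the same replicate number correlated between the tissues (0.117 to 0.322, other pairs -0.201 to -0.01). Noise shared within a replicate is therefore not excluded for this overlap. Without 1 pupal VNC library, the genes lower in both numbered 1, 2 and 3 (control 1, 2 and 3) and 7, 17 and 4 (MeHg 1, 2 and 3). They included GstE13, l(2)37Cd (log2 -2.30 in IFM and -1.18 in VNC), KFase (-2.25 and -1.74), Ada (-2.40 and -1.73) and PolD2 (-1.92 and -1.20), of which KFase, Ada and PolD2 were chosen after their values were seen. KFase and Ada lay below the 5 CPM of the naming rule (values scaled over all 24 libraries). Over both tissues KFase ran from 2.221 to 3.298 CPM in pupal controls and from 0.3932 to 1.206 with MeHg. Ada ran from 1.268 to 2.118 and from 0.2449 to 0.4638. In adults 3 genes were called in both tissues (expected 0.6), CNMa, CG43402 and CG4757. Pupal and adult IFM shared 38 called genes (expected 25.9), 10 with opposite signs, and pupal and adult VNC shared 2 (expected 0.04), Cep290 and CG34215. Of the 340 genes called in pupal IFM and tested in both tissues 257 had the same sign in pupal VNC (75.6%, Pearson 0.519 among them), and in adults 409 of 813 (50.3%, 0.292). Over all genes, Pearson correlations of log2 fold changes across genes were -0.008 between tissues in pupae, -0.076 in adults, -0.086 between stages in IFM and -0.267 in VNC. Spearman correlations were 0.09, -0.079, 0.034 and -0.176 in the same order, so the sign depended on the measure between tissues in pupae and between stages in IFM. Genes are not independent replicates, so no p is given.

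**Figure D5:**
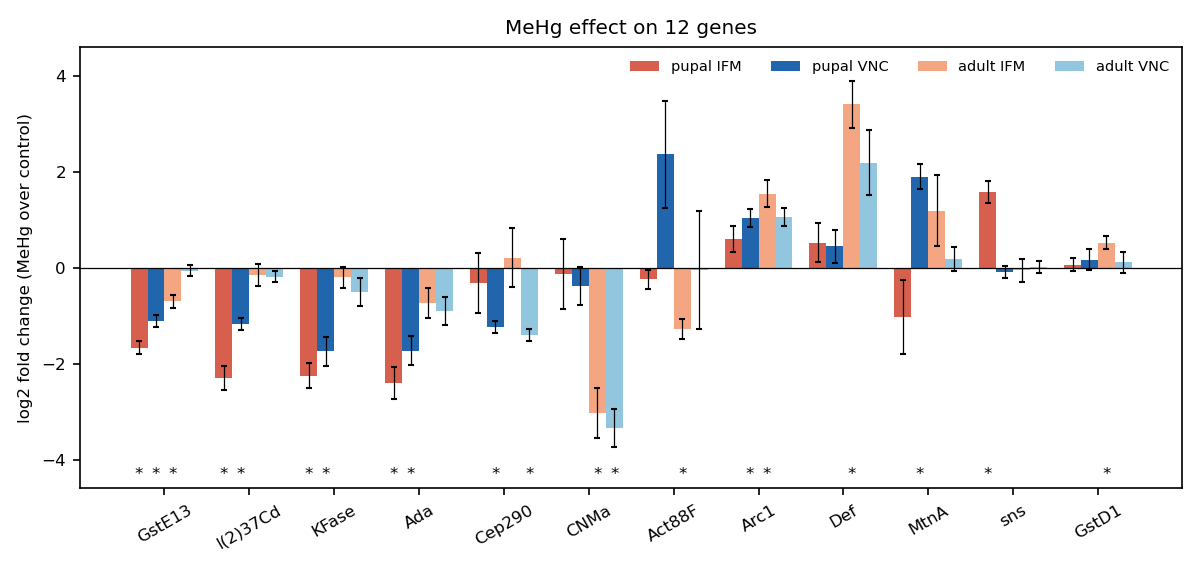
Log2 fold change of MeHg over control (vertical axis) of 12 genes (horizontal axis) in the 4 comparisons, bars with standard errors; an asterisk marks an adjusted p under 0.05. GstE13 fell in pupal IFM, pupal VNC and adult IFM, and CNMa in both adult tissues.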

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

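The tests of gut RNA, sex and gene length in adult IFM, of gene length and the state of development in pupal IFM, and of the 11 genes lower in both pupal tissues were chosen after the calls had been seen, the test of a strain variant was written after its values were known, and the rules that judge them were made stricter after their values were seen.

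The difference of the MeHg response between groups was tested itself (edgeR quasi-likelihood, adjusted p under 0.05). It passed between adults and pupae for 305 genes in IFM and for 1 gene in VNC, CG34215, and between IFM and VNC for 31 genes in pupae and 427 in adults. The splits redraw MeHg and control within each group, so a split that keeps the real labels in 1 group still carries its MeHg effect, and the counts say whether calls arise without that effect, not whether the effects differ. For the stage difference in IFM 1 of 40 splits, the real one with 305, gave as many, and the highest other gave 101. No other drawn split thus reached the count of the real labels. The real split is always among the 40, so 1 of 40 is the lowest share possible. As 4 differences were examined without adjustment, chance is not excluded by this share. The difference itself stays open, since the count was 0 with the title tag as a batch term, which in adult IFM differs only for MeHg 4, and 18 with a replicate block. In VNC the real split gave 1 gene and the highest other 0 (1 of 40), and 1 gene, lost without pupal VNC control 1, decides nothing. For the tissue difference in adults 1 of 40 gave as many as the real 427, but the splits with 420, 275, 237 and 153 genes kept the real labels in IFM, so these counts carry the MeHg effect in IFM, and whether it differs between the tissues stays open. For the tissue difference in pupae 5 of 40 gave as many as the real 31, so chance is not excluded by this count. The 4 others (490, 220, 57 and 32) also kept the real labels in IFM, and that with 490 swapped them in VNC, which adds both MeHg effects, so they carry the treatment and no conclusion is drawn from them.

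The first pattern weighed is the lower median of the oxidative phosphorylation list (3 of 69 genes called) and the higher median of the fusion list (5 of 24) in pupal IFM, neither of which passed with the estimated correlation (adjusted p 0.474 and 0.164), and where long genes had gained relative to short ones in the MeHg libraries. With the length trend of each library removed the median log2 fold change went from -0.331 to -0.149 for oxidative phosphorylation and from 0.434 to 0.264 for fusion, so a length bias may account for part of both, and the share left cannot be told apart from an imperfect correction. A younger state at dissection was taken to move genes against the change from pupa to adult. The correlation of the MeHg effect with that change across genes was 0.087, within the 0.073 to 0.146 of simulations without an effect. Simulated values lie above 0 because both effects share the pupal controls. An earlier bound of this test (a correlation above 0) was wrong for that reason. The other bound, a covariance at or above the simulated one, allows for the shared controls. The covariance was 0.181, within the 0.118 to 0.246 simulated (mean 0.177), so the fall predicted for a younger state was not seen. A small shift inside that range is not excluded, and the state at dissection cannot be told apart from an effect of MeHg. The reference spans pupae at 30 h and adults at 15 days, and a delay of hours need not run against it. The test therefore cannot decide, and no conclusion on the state at dissection is drawn from it. An effect of MeHg on the muscle, which the design names, stays open.

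The second pattern is the calls of adult IFM, where roX1 rose with MeHg and the gut list was called higher with the preset correlation but not with the estimated one (adjusted p 0.723), while Sxl, Yp1, Yp2 and Yp3 lay lower with separate ranges without passing and the ranges of roX2 overlapped. With the gut list as covariate the median of the 446 lower genes went from -0.622 to -0.463 (17 still called, standard error 0.136 to 0.162) and that of the 416 higher genes from 1.315 to 1.118 (33 still called, 0.252 to 0.293). With roX1 as covariate the medians were -0.634 (0 still called, standard error 0.219) and 1.107 (4 still called, 0.407), and with roX1 calls ended mainly as the errors grew, since roX1 runs with the groups. With the gut list both medians shrank and the errors grew. With the length trend removed the lower genes had a median of -0.524 and 346 of 446 were still called, which argues against length as their whole cause. With roX1 the lower genes kept 1.019 of their median and the higher genes 0.842, and with the gut list 0.743 and 0.851. The rule first set asked only for this share, and all but the 0.743 would have counted against the cause. That rule left out the standard errors, and beside these errors the shares do not decide. Gut RNA or a larger share of males may contribute, and neither can be told apart from an effect of MeHg here.

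The third pattern is the 11 genes lower in both pupal tissues. Of 100 combinations of splits 1, the real one, shared as many, and the highest other shared 0, but the other splits called 0 genes in either tissue, so this says little about the overlap itself, and MeHg pupae of the same replicate number correlated between the tissues (0.117 to 0.322). With the length trend removed 8 of the 11 were still called in both tissues (over 26 alternatives the number of genes called lower in both ran from 0, with a replicate block or the 6 libraries alone, to 43 with DESeq2; leaving out 1 pupal VNC library gave 1, 2 and 3 without control 1, 2 and 3, and 7, 17 and 4 without MeHg 1, 2 and 3), and the part lost cannot be told apart from a length effect. A strain variant carried by the MeHg cultures would lower the genes in adults too, where their median was -0.173 (SD 0.319) against -1.176 in pupae, but the labels do not say whether pupae and adults came from the same cultures, so a variant cannot be told apart from a pupal effect of MeHg.

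For the comparisons of 3 against 3 samples the 10 splits are too few for a share under 0.05. The real split was the 1 with as many genes in each: pupal IFM 341 (highest other 0), pupal VNC 63 (0), adult IFM 862 (1), adult VNC 8 (6), stage in control IFM 8445 (0) and VNC 7627 (0), and tissue in control pupae 7576 (0) and adults 9225 (0).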

How the results depend on the processing

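The removal of the length trend, the covariates, the pairs of libraries left out and all alternatives for the average effect and the 11 shared pupal genes were chosen after the results had been seen. Over the alternatives chosen before, named gene results gave 3300 values, of which 2519 kept call and direction. Genes that were not called and stayed so count as kept. The call was lost in 744, gained in 5 and reversed in 0, and in 32 an uncalled gene changed sign. Kept and lost values were 541 and 207 of 750 in pupal IFM and 291 and 120 of 419 in pupal VNC. They were 913 and 406 of 1330 in adult IFM and 154 and 7 of 177 in adult VNC. Stage and tissue comparisons kept nearly all values (153 to 156 of 156 each). Over the alternatives added later 648 of 1074 values kept call and direction, 401 lost the call and 0 reversed, and in 23 an uncalled gene changed sign. Called lists kept both in 235 of 310 values, lost the call in 72 and reversed in 3, where reversed means that camera gave the other direction (pupal VNC neurons and glycolysis without MeHg 2, antimicrobial genes without MeHg 3). The median also turned, without camera's direction, for the sarcomere in adult VNC (0.086 without control 3, 0.017 without MeHg 4). Stage and tissue counts stayed within 1.5-fold, but their balance turned with RLE scaling for tissue in adults (4849 higher, 4478 lower) and stage in VNC (3928, 3815). The cause of each change below was not tested, except where samples were left out or terms added, which leaves fewer degrees of freedom.

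DESeq2 called 949 genes in pupal IFM, 224 in pupal VNC, 1522 in adult IFM, 276 in adult VNC, and 1010, 219, 258 and 1177 for the interactions (stage in IFM, in VNC, tissue in pupae, in adults), and it also called 20 to 39 unchanged genes in simulated data without a length trend, where edgeR called 0 to 7. With a length trend of 1 strength simulated into the MeHg libraries, edgeR called more unchanged genes. They numbered 51, 169, 108 and 174 in pupal IFM, pupal VNC, adult IFM and adult VNC, and 3, 6, 7 and 11 with the trend removed. Voom called 873, 101 and 88 in pupal IFM, pupal VNC and adult VNC, and 4 and 945 for stage in VNC and tissue in adults. RLE scaling gave 2 for stage in VNC and 59 for tissue in pupae, and no filter 30 in pupal VNC and 283 for tissue in adults. A replicate block gave 0, 0, 331 and 2 for the 4 MeHg effects and 18 for stage in IFM. Replicates of the same number did not correlate beyond others in pupal IFM (-0.289 to 0.054) and pupal VNC (-0.112 to -0.017), so losses there are no measure of the effect; in adult VNC the 2 shared numbers did (0.342 and 0.345), as did IFM with VNC in MeHg pupae (0.117 to 0.322), and no comparison was fitted as paired. The title tag as batch gave 154, 31 and 81 in pupal IFM, pupal VNC and adult IFM, 8 in adult VNC of which 1 was among the main 8, 0 and 5 for stage in IFM and VNC, and 275 for tissue in adults. The replicate block called 1 gene for stage in VNC, another than the main one. The 6 libraries alone gave 523, 0, 152 and 27 (3 of the main 8 in adult VNC), and all 24 gave 587, 28 (1 higher, 27 lower) and 1410 in pupal IFM, pupal VNC and adult IFM.

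Covariates gave 94 (neuron list) and 128 (roX1) in pupal IFM, 25 (gut), 13 (sarcomere) and 31 (roX1) in pupal VNC, 50 (gut) and 6 (roX1) in adult IFM, and 5 (testis), 3 (sarcomere), 0 (roX1) and 12 (gut, 10 higher, with 1 of the main 8) in adult VNC. Without the 2 libraries of unusual markers 66 were called in pupal IFM (control 2, MeHg 2), 37 in adult IFM (control 3, MeHg 4) and 24 in adult VNC (control 2, MeHg 1). Length removal gave 5 for stage in VNC. With each library left out the range was 101 to 271 in pupal IFM, 5 to 84 in pupal VNC, 210 to 1080 in adult IFM, 2 to 25 in adult VNC, 39 to 447 and 0 to 11 for stage in IFM and VNC, and 16 to 56 and 141 to 716 for tissue in pupae and adults.

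With the estimated correlation 0 lists passed in each of the 4 MeHg comparisons, against 12, 8, 8 and 3, and the 6 libraries alone gave 5 in pupal VNC. In pupal VNC, medians with 1 library left out ran from -0.215 (without MeHg 1) to 0.001 (without MeHg 2) for neurons, 0.078 (without MeHg 3) to 0.459 (without MeHg 1) for antimicrobial genes and -0.001 (without MeHg 2) to 0.117 (without MeHg 1) for glycolysis. Length removal reversed the proteasome in pupal IFM (0.032) and ribosomal proteins in adult IFM (0.067).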

Other observations

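The average MeHg effect over both tissues and stages, with its splits, was tested only after the single comparisons had been seen. It was fitted on all 24 libraries (edgeR quasi-likelihood, 12631 genes) and called 683 genes, 206 higher and 477 lower, of which 325 had 1 sign in all 4 comparisons. Of 40 splits 1, the real one, gave as many, and the highest other gave 547. No conclusion is drawn from this, since splits can keep the real labels in part of the groups, and since the fit and its splits take IFM and VNC libraries as independent, whereas MeHg pupae of the same replicate number correlated between the tissues (0.117 to 0.322, other pairs -0.201 to -0.01). GstE13 fell by 0.91 ± 0.06 (log2, adjusted p 1.44e-07), with -1.66, -1.12, -0.70 and -0.06 in pupal IFM, pupal VNC, adult IFM and adult VNC, so hardly in the last. Arc1 rose by 1.04 (adjusted p 0.000112), with 0.60, 1.03, 1.55 and 1.05 in the same order. GstE13 and Arc1 were named from the called genes with 1 sign in all 4 comparisons, so their shared sign was given by that choice. In adult IFM, Arc1 varied between MeHg replicates 1, 3 and 4 (3528, 8126 and 3639 CPM, scaled over all 24 libraries). The count was 860 with RLE scaling (414 higher, 446 lower), 1430 with DESeq2, 779 with the length trend removed and 504 with a replicate block, and 467 (without adult IFM MeHg 4) to 1182 (without pupal VNC MeHg 2) with 1 library left out.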
